A study of Arabidopsis thaliana with 24 samples.

How the data were processed

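The series holds 24 libraries of polyadenylated RNA from Arabidopsis thaliana seedlings of the accession Columbia-0, WT or pifq, in darkness or light, with ABA or mock, 3 biological replicates per group. Per the labels, seeds were stratified for 2 days. Dark-grown seedlings received a 2 h light pulse, were transferred after 62 h and stayed 4 more days in darkness. Light-grown seedlings stood in 10 µmol m-2 s-1 of white light with 16 h light and 8 h dark, were transferred after 72 h and stayed 5 more days. All grew at 22 °C, and the times hold unless otherwise stated. Libraries were stranded and read as paired ends of 100 bases on a DNB-seq instrument. The authors deposited 1 table of raw read counts per gene, and the values were checked to be whole numbers with unequal column sums. The submitters' processing notes name FastQC, STAR, SAMtools, DESeq2 and the genome TAIR10 without versions. The counting program, strand setting and annotation release are not given in the sources used here. Gene names were taken from the reference annotation of TAIR10.1, and no coordinates are reported.

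The table held 32833 genes, of which 4822 had no count in any library. Of these, 285 were not matched in the reference (133 chloroplast and 152 mitochondrial genes, 0.775% of counts). They stayed in the model. Totals lay between 13722850 and 17538529 counts, and group means between 14420959 in pifq light ABA and 16961913 in WT dark mock. In the smallest library 1 count is 0.0729 CPM and 3 counts are 0.219 CPM. Between replicates of a group, counts differed by 4.23 to 21.0 times the chi-square per degree of freedom of counting error alone, so replicates varied more than counting error. The median biological coefficient of variation was 0.109.

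R 4.3.3 and edgeR 4.0.16 were used. Genes passing filterByExpr by group (20828) were scaled by the trimmed mean of M-values (TMM) and fitted by robust quasi-likelihood with 1 coefficient per group in all 24 libraries (16 residual degrees of freedom). There were 15 contrasts: ABA against mock in each genotype and light, pifq against WT in each light and treatment, light against darkness in mock for each genotype, and 5 interactions, those of ABA with light in WT, of ABA with genotype in darkness and in light, of genotype with light in mock, and of all 3 factors. P-values were adjusted by Benjamini-Hochberg within a contrast, and a gene with adjusted p under 0.05 was called. The standard error of a log2 change is its size divided by the square root of the quasi-likelihood F. Levels are TMM-scaled CPM. Principal components were taken of log2 CPM with a prior count of 2.

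Lists of 24 gene groups were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 360 tests of 24 lists in 15 contrasts. A list was called at adjusted p under 0.05, and the adjusted p with a correlation estimated from the data is given beside it. The lists, the tests, the contrasts, the alternatives and the rule for named genes were fixed before the data were examined; 3 alternatives were added afterwards (a replicate block fitted to the compared samples only, the SAUR list without SAUR19 to SAUR24, and the SAUR list without a gene named SAUR21 whose product is an ARM repeat protein). The lists hold known members of each pathway, not genes chosen on these samples, and lists of seed, root and leaf epidermis markers follow tissues. Named genes were the 5 highest and 5 lowest of 6 main contrasts and the 3 highest and 3 lowest of the others, with a symbol, a mean of at least 5 CPM and groups that do not overlap, and the 4 list members of lowest p per contrast. Of 20 ways to order 3 libraries against 3, 2 keep the groups apart, so chance alone gives non-overlap to 10% of genes.

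A change against a group with no counts is given as at least a fold, computed with 3 counts over that group. With 1 to 3 counts over the group, the ratio of counts per total is given with its exact conditional 95% interval, which covers counting error only. No size is given for an interaction with such a group. The overlap of 2 contrasts that share libraries is given beside the expectation for independent lists and 10 simulations from the fitted dispersions. These held no effects, so only shared libraries tied them. The dark mock group of 3 libraries cannot be split into parts of at least 2 libraries each. Libraries of compared groups carry the same replicate numbers in the labels, which do not say that a number marks a shared batch. The deviations of same-numbered libraries from their group means were correlated over genes; every one of the 3 r values lay above 0.1 only for pifq against WT in dark mock (0.13, 0.15 and 0.32) and under light ABA (0.39, 0.51 and 0.34), so that there the numbers were taken to pair the libraries.

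The steps were tested on simulated data with 200 planted changes. For ABA in WT dark, edgeR recovered 50.0% of 1.5-fold changes (30 of 60), 64.4% of 2-fold changes (47 of 73) and 95.5% of 4-fold changes (64 of 67), with 6 false calls. For ABA by genotype in darkness it recovered 23.3%, 52.1% and 86.6%, with 5 false calls. Each of 3 list tests called a planted list and 0 of 23 random lists. Correlated lists were not tried. Alternatives were median-of-ratios (RLE) size factors, scaling by library totals alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit of only the samples compared, no organelle genes, an added limit of 2-fold, each library left out in turn, and for lists an estimated correlation, fry and the replicate block. No library and no gene with counts above the filter was left out of the main test.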

Results

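Polyadenylated RNA was measured in whole seedlings of Arabidopsis thaliana, accession Columbia-0. The wild type (WT) was set beside pifq, a mutant in the transcription factor genes PIF1, PIF3, PIF4 and PIF5. These factors promote seedling elongation in darkness and are inactivated by phytochromes in light. Seedlings of each genotype grew in darkness or in white light of 10 µmol m-2 s-1 and were moved to plates with abscisic acid (ABA), a hormone that inhibits growth, or with ethanol as mock. The transfer was made after 62 h in darkness or 72 h in light. The treatment lasted 4 days in darkness and 5 days in light, times that per the labels hold unless otherwise stated. Light and age are therefore not separated in this design. The dose of ABA is not given in the sources used here. The 8 groups of genotype, light and treatment held 3 biological replicates each, 24 libraries in all. Total counts per library lay between 13722850 and 17538529, and 20828 genes had enough counts to be tested. After a log2 change, ± gives its standard error, and after a level in CPM (counts scaled to library size) the standard deviation of 3 libraries. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each gene list is followed by the adjusted p of the camera test with a preset correlation, and for called lists by the adjusted p with a correlation estimated from the data. Counts of called members adjusted over the list alone are given where they differ from the counts over all genes tested. Intervals of folds cover counting error only.

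The genes mutated in pifq were examined first in every library. PIF3 stood at 55.9 to 71.2 CPM in the 3 WT libraries of dark mock and at 1.67 to 3.1 CPM in the 3 pifq libraries. PIF5 stood at 34.0 to 39.9 against 12.7 to 20.9 CPM. In light mock PIF3 was at 28.3 to 46.3 CPM in WT and 0.873 to 2.64 CPM in pifq, and PIF5 at 179.5 to 225 against 28.5 to 33.5 CPM. Both genes were lower in every pifq library than in every WT library of the same light and treatment, which goes with the labels. PIF1 and PIF4 were higher in the dark mock libraries of pifq, PIF1 at 84.2 to 98.6 CPM against 36.8 to 38.2 CPM in WT. The levels of PIF4 were 49.0 to 75.2 CPM in pifq and 29.8 to 34.5 CPM in WT. An insertion allele can leave transcript upstream or downstream of the insertion, so the counts of PIF1 and PIF4 check no label. In light mock PIF4 was lower in pifq, at 105 to 118 CPM against 214 to 257 CPM in WT.

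**Figure D1:**
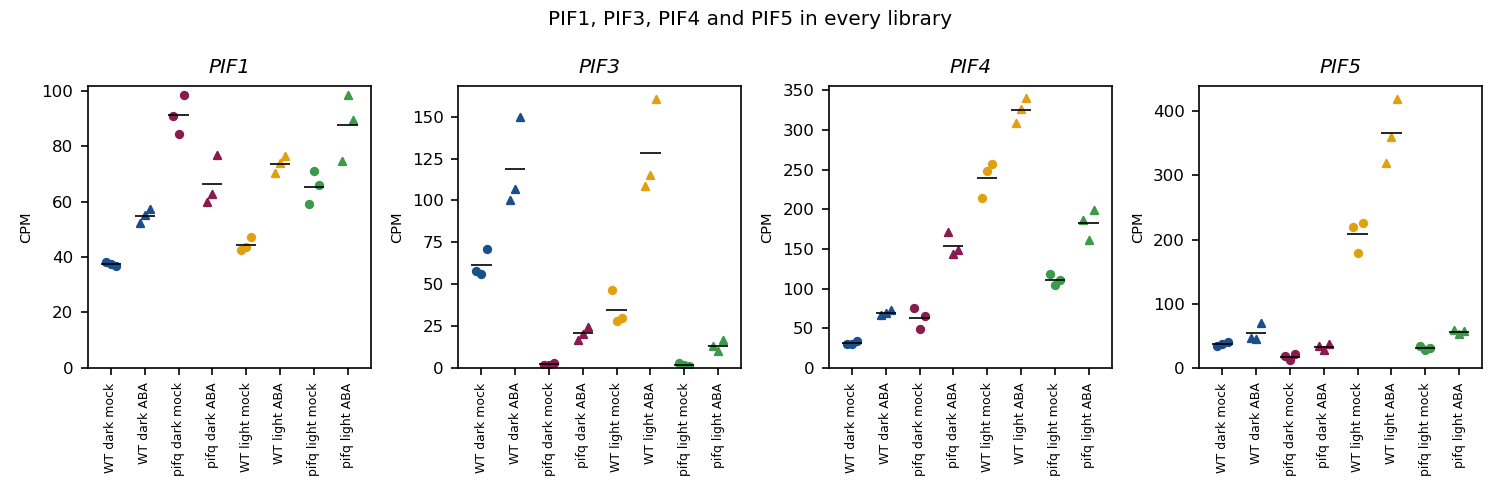
Level in CPM (linear axis) of PIF1, PIF3, PIF4 and PIF5 in each of the 24 libraries, by group. Points are libraries (circles mock, triangles ABA) and black lines group means of 3. PIF3 and PIF5 lie lower in pifq than in WT in each light and treatment, and PIF1 and PIF4 lie higher in pifq than in WT in dark mock.

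Light and ABA parted the libraries. The first principal component of log2 CPM took 42.4% of the variance and ran from WT in darkness (-114.7 to -80.6) through pifq in darkness (-54.6 to -27.4) to both genotypes in light (50.4 to 92.3). The second took 36.1% and parted the 12 mock libraries (47.5 to 83.3) from the 12 ABA libraries (-78.9 to -57.0). The share of counts from mitochondrial genes moved with the groups as well, from 0.224% ± 0.0381 (SD, n = 3) in WT dark mock and 0.195% ± 0.0327 in WT dark ABA to 0.127% ± 0.0262 and 0.115% ± 0.0215 in pifq in darkness. It lay between 0.0362% ± 0.00540 and 0.0558% ± 0.00550 in the 4 light groups.

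**Figure D2:**
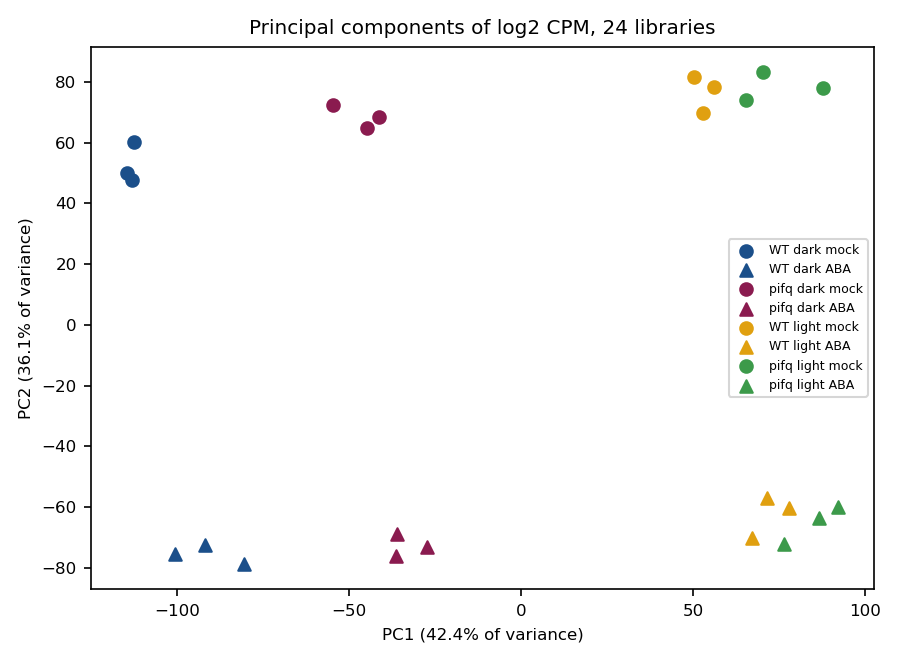
Scores of the 24 libraries on the first and second principal components of log2 CPM. Colour gives genotype and light, circles are mock and triangles ABA. WT and pifq libraries lie apart along the first component in darkness, by less in light mock (50.4 to 56.0 against 65.4 to 87.7) and overlap in light ABA (67.0 to 78.0 against 76.6 to 92.3).

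The response of WT to ABA in darkness was the first comparison, because the title of the series concerns ABA and elongation in darkness. ABA raised the genes of its own response and of the seed. All 21 measured ABA-induced effector genes rose (camera adjusted p = 1.82e-25, adjusted p = 0.006 with estimated correlation). Among them were the homeodomain gene ATHB7, with a log2 change of 2.89 ± 0.16, the transcription factor gene ABF2, which acts in ABA signalling, with 1.89 ± 0.11, and the alcohol dehydrogenase gene ADH1, with 2.51 ± 0.17. All 9 clade A PP2C phosphatases, which restrain ABA signalling, rose as well (camera adjusted p = 6.59e-31, adjusted p = 0.000105 with estimated correlation). HAI3, one of them, went from 0.778 ± 0.145 to 119 ± 10.8 CPM. Of 12 genes of ABA synthesis and catabolism, 10 rose and none fell (camera adjusted p = 9.44e-08, adjusted p = 0.00222 with estimated correlation). They included CYP707A4 (4.88 ± 0.36) and CYP707A2 (3.40 ± 0.20), which degrade ABA, as well as ABA1 (1.72 ± 0.16), a zeaxanthin epoxidase gene of ABA synthesis. Of 9 ABA receptor genes, 6 fell and 1 rose (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00437, adjusted p = 0.137 with estimated correlation). PYL6 (-3.24 ± 0.61) and PYL4 (-1.58 ± 0.17) were among those that fell. Genes of seed storage and oil bodies rose in 11 of 11 (camera adjusted p = 0.000113, adjusted p = 0.384 with estimated correlation). CRU3, which encodes the storage protein cruciferin, went from 4.57 ± 3.11 to 1195 ± 878 CPM (adjusted p = 9.82e-05). Of 2 caleosin genes of oil bodies, ATPXG2 was 637-fold higher (95% counting interval 218 to 3093) and ATS1 was 649.9-fold higher (95% counting interval 179.5 to 5373), or 375-fold without the first replicate of WT dark ABA.

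Several genes nearly vanished with ABA in darkness. IRT1, the iron transporter of the root epidermis, fell from 355 ± 129 to 0.321 ± 0.395 CPM (adjusted p = 1.97e-10). AGP30, an arabinogalactan protein gene, fell from 169 ± 5.79 to 0.558 ± 0.859 CPM. Counts in the 3 ABA libraries were 14, 1 and 2 for IRT1 and 28, 1 and 1 for AGP30. AIR1, an auxin-induced gene of root cultures, was 1548-fold lower (95% counting interval 428 to 12787). The cytokinin oxidase gene CKX4 was 1049-fold lower (95% counting interval 188 to 41466) and the expansin gene EXPA17 was 629-fold lower (95% counting interval 215 to 3054). Among 13 markers of root endodermis and root hairs, 8 fell and 1 rose (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.000456, adjusted p = 0.371 with estimated correlation). EXPA18 (-5.47 ± 0.79) and PRP3 (-3.45 ± 0.55), both of root hairs, were among those that fell, EXPA18 to 1, 0 and 3 counts. No list of growth genes was called as a whole. Of 64 measured SAUR genes, which encode small proteins that promote cell expansion, 14 fell and 6 rose (5 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.0618). SAUR37 was 111-fold lower (95% counting interval 30.5 to 926). SAUR76 fell by 6.2 ± 0.51 on the log2 scale and SAUR33 rose by 1.49 ± 0.23. The number of SAUR genes that fell was 9 without the first replicate of WT dark mock. Of 25 expansin and XTH genes, which loosen cell walls, 5 rose and 3 fell (4 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.975). The PIF-induced genes gave 2 higher and 2 lower of 14 (camera adjusted p = 0.689). The auxin genes gave 1 higher and 3 lower of 24 (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.643).

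Among the other groups, 6 of 10 genes of dark starvation and senescence rose and 1 fell (camera adjusted p = 0.00585, adjusted p = 0.179 with estimated correlation). PAO (1.68 ± 0.11), which opens the chlorophyll ring, was among those that rose. Of 10 mitotic genes, 6 fell and none rose (0 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0292, adjusted p = 0.634 with estimated correlation). The cyclin gene CYCA1;1 (-1.08 ± 0.24) and the kinase gene CDKB2;2 (-0.91 ± 0.18) were among them. The PIF family rose in 6 of 7 members (camera adjusted p = 0.0104, adjusted p = 0.135 with estimated correlation). The remaining lists were not called by camera. Gibberellin genes gave 5 higher and 2 lower of 18 (camera adjusted p = 0.534), PP2C.D phosphatases and proton pumps 6 and 2 of 15 (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.286). Ethylene and hook genes gave 2 and 0 of 9 (camera adjusted p = 0.897). Nuclear photosynthesis genes gave 0 and 3 of 26 (camera adjusted p = 0.178), chlorophyll genes 2 and 0 of 14 (camera adjusted p = 0.695). Photomorphogenesis regulators gave 2 and 1 of 15 (camera adjusted p = 0.689). Brassinosteroid genes gave 0 and 2 of 12 (camera adjusted p = 0.914), flavonoid genes 4 and 1 of 10 (camera adjusted p = 0.452). Jasmonate genes gave 1 and 1 of 7 (camera adjusted p = 0.772). Heat shock genes gave 1 and 3 of 7 (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.289) and stomatal lineage genes 1 and 1 of 9 (camera adjusted p = 0.722). Median, mean and camera differed in sign for the expansins (median 0.158, mean 0.06, camera lower), brassinosteroid (0.106, -0.023, lower), flavonoid (-0.394, 0.032, higher), photomorphogenesis (0.066, -0.056, higher) and jasmonate genes (0.062, -0.286, lower), so none of these lists is given a direction. Scaled by library totals alone, the balance of calls changed for the expansins and XTH (2 higher and 4 lower), the ethylene and hook genes (0 higher and 1 lower) and the gibberellin genes (2 higher and 2 lower). With RLE size factors it changed for the expansins and XTH (4 higher and 4 lower). Over all genes, edgeR called 8385 of 20828 genes (4744 higher and 3641 lower) with n = 3 per group, 1144 of them higher and 1870 lower by at least 2-fold. Of the calls, 56.6% were higher, against 34.9% when libraries were scaled by their totals alone (2720 higher and 5077 lower).

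In light, ABA raised the same lists of ABA response and lowered many members of the growth lists in WT. The ABA-induced effector genes rose in 21 of 21 (camera adjusted p = 1.76e-27, adjusted p = 0.00321 with estimated correlation). The clade A PP2C phosphatases rose in 9 of 9 (camera adjusted p = 8.33e-32, adjusted p = 0.000105 with estimated correlation), HAI2 by 7.14 ± 0.34. ABA synthesis and catabolism gave 9 higher of 12 (10 higher and 0 lower adjusted over the list alone, camera adjusted p = 2.08e-09, adjusted p = 0.000721 with estimated correlation). The ABA receptors gave 7 lower of 9 (camera adjusted p = 7.34e-07, adjusted p = 0.0122 with estimated correlation). Seed genes with at most 3 counts in the mock libraries appeared. BETA-TIP, a tonoplast aquaporin of seeds, was at least 201-fold higher, the albumin gene SESA3 at least 153-fold higher, the late embryogenesis gene ATECP31 at least 143-fold higher. SESA5 was 996-fold higher (95% counting interval 275 to 8230.3) and the metallothionein gene AtMT4b 1029-fold higher (95% counting interval 184 to 40683). The second replicate of WT light ABA held 393 of 418 SESA3 counts of that group. Without it the bound was 13.7-fold, without the first replicate 235-fold. SESA3 was not called without that second replicate (adjusted p = 0.313) nor without any of the 3 mock libraries in turn (adjusted p = 0.0548 to 0.0576). SESA5 was 287-fold higher without the second replicate of WT light ABA. Of the seed storage list 10 of 11 rose (11 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.000245, adjusted p = 0.393 with estimated correlation).

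Of the 64 SAUR genes, 30 fell and 10 rose in WT light (camera adjusted p = 0.0408, adjusted p = 0.634 with estimated correlation). SAUR1 fell from 5.51 ± 1.66 to 0.535 ± 0.308 CPM, whereas SAUR74, at 3.13 ± 0.34, was among those that rose. Expansin and XTH genes fell in 13 and rose in 3 of 25 (3 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.384 with estimated correlation). The expansin genes EXPA8 (-1.78 ± 0.20) and EXPA1 (-1.88 ± 0.16) fell. Auxin genes fell in 11 and rose in 3 of 24 (3 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.0238, adjusted p = 0.605 with estimated correlation). IAA29 changed by -3.45 ± 0.45, IAA6 by -3.40 ± 0.48 and IAA19 by -3.02 ± 0.36, and all encode auxin-response repressors. Mitotic genes fell in 8 of 10 (0 higher and 9 lower adjusted over the list alone, camera adjusted p = 3.57e-05, adjusted p = 0.319 with estimated correlation). Stomatal lineage genes fell in 6 and rose in 1 of 9 (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00473, adjusted p = 0.215 with estimated correlation). Root markers fell in 7 of 13 (camera adjusted p = 0.00115, adjusted p = 0.383 with estimated correlation). The largest falls by the rule for named genes included CRK30, a receptor-like kinase gene, 358-fold lower (95% counting interval 98.9 to 2964). CKX4 was 232-fold lower (95% counting interval 79.2 to 1129). CYP705A5, a cytochrome P450 gene, was 145-fold lower (95% counting interval 39.8 to 1201). DR4 changed by -6.85 ± 0.55 and CYP735A2, which makes trans-zeatin, by -6.19 ± 0.34 (adjusted p = 1.57e-11). In all, edgeR called 8327 of 20828 genes (4380 higher and 3947 lower) with n = 3 per group, 1352 higher and 2087 lower by at least 2-fold. Of the calls, 52.6% were higher, against 35.0% when libraries were scaled by their totals alone (2901 higher and 5383 lower).

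Whether WT responded otherwise to ABA in light than in darkness was tested as the interaction of ABA and light. SAUR1 stood at 8.68 ± 0.616 CPM in dark mock and 9.80 ± 1.58 CPM in dark ABA. With its fall in light, the interaction was -3.53 ± 0.48 (adjusted p = 4.91e-05). The expansin genes EXPA5 (-2.99 ± 0.44) and EXPA8 (-2.00 ± 0.28) and the auxin repressor genes IAA6 (-3.58 ± 0.54) and IAA29 (-3.26 ± 0.59) likewise responded lower in light than in darkness. In the other direction, PRP3 (3.82 ± 0.70), EXPA18 (5.21 ± 0.97) and AGP30 (5.53 ± 1.12) responded higher in light, having fallen in darkness, as did BGLU35, a beta-glucosidase gene (5.15 ± 1.03). Without the first replicate of WT dark ABA the value of AGP30 was 8.63. BETA-TIP, AIR1 and EXPA17 were called higher as well (adjusted p = 0.00045, adjusted p = 0.0235 and adjusted p = 0.00109), with at most 3 counts in a group of each, so no size is given. AIR1 was not called without 2 of 12 libraries taken out in turn (adjusted p = 0.148 to 0.163). Among the lowest here were MSRB7, a methionine sulfoxide reductase gene (-4.35 ± 0.77), and FBA5 (-3.76 ± 0.98), an aldolase gene. So were the pectin methylesterase genes ATPMEPCRD (-4.06 ± 0.49) and PME61 (-3.57 ± 0.65), and GER3 (-3.66 ± 0.88), a germin-like gene. FBA5 was not called without the third replicate of WT dark ABA (adjusted p = 0.142).

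Of the SAUR genes, 11 responded lower and 9 higher in light than in darkness (13 higher and 19 lower adjusted over the list alone, camera adjusted p = 0.766). The number lower was 17 without the first replicate of WT dark ABA, 7 without the second replicate of WT dark mock and 7 without the second replicate of WT light ABA. With RLE size factors the SAUR genes gave 10 higher and 10 lower. The expansins and XTH gave 6 lower and 1 higher (3 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.000885, adjusted p = 0.217 with estimated correlation). The auxin genes gave 6 lower and 0 higher (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.542 with estimated correlation). Mitotic genes gave 3 lower and 0 higher (camera adjusted p = 0.0123, adjusted p = 0.592 with estimated correlation). The stomatal lineage gave 3 lower and 1 higher (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00513, adjusted p = 0.22 with estimated correlation). The ABA receptors gave 3 lower (camera adjusted p = 0.0334, adjusted p = 0.314 with estimated correlation), PYL4 with -1.56 ± 0.24. edgeR called 2480 of 20828 genes (1226 higher and 1254 lower) with n = 3 in each of 4 groups. Across all tested genes, which are not independent replicates, the ABA responses in darkness and light had a Pearson r of 0.728 and a Spearman rho of 0.617. Of the calls, 2688 genes rose in both, against 998 for independent lists, and 2144 fell in both, against 690. There were 234 called in opposite directions, against 1665. These comparisons share no library.

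In darkness without ABA, pifq differed from WT in genes of greening and of the PIF pathway. Nuclear photosynthesis genes were higher in 25 of 26 (camera adjusted p = 2.64e-19, adjusted p = 0.135 with estimated correlation). LHCB6, a light-harvesting protein gene, was at 510.0 ± 58.4 CPM against 102 ± 29.1 CPM in WT. Genes of chlorophyll synthesis and greening were higher in 13 and lower in 1 of 14 (camera adjusted p = 4.07e-12, adjusted p = 0.0756 with estimated correlation). PORC, a protochlorophyllide reductase gene, changed by 2.26 ± 0.17, and PORA, the protochlorophyllide reductase of etiolated seedlings, was the one that was lower. All 9 stomatal lineage genes were higher (camera adjusted p = 1.58e-09, adjusted p = 0.0085 with estimated correlation). They included SPCH, which starts the lineage (2.56 ± 0.20), and the receptor gene TMM (1.81 ± 0.16). Of 14 PIF-induced growth and shade genes, 10 were lower and 1 was higher (camera adjusted p = 4.04e-10, adjusted p = 0.0175 with estimated correlation). PIL1 went from 39.2 ± 3.41 to 1.88 ± 0.739 CPM (adjusted p = 5.47e-11). Of the SAUR genes 24 were lower and 6 higher in pifq (camera adjusted p = 0.00103, adjusted p = 0.392 with estimated correlation). SAUR9 (-2.30 ± 0.28) and SAUR36 (-1.14 ± 0.14) were among those that were lower.

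Heat shock genes were lower in pifq dark mock in 6 of 7 (0 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00243, adjusted p = 0.359 with estimated correlation). Root markers were lower in 9 of 13 (0 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.00192, adjusted p = 0.401 with estimated correlation), CASP5 with -2.21 ± 0.28. Brassinosteroid genes were lower in 6 and higher in 1 of 12 (camera adjusted p = 0.0414, adjusted p = 0.495 with estimated correlation). The highest single genes were CRK30 (5.12 ± 0.30), the orphan gene QQS (5.02 ± 0.41), the microRNA genes MIR5026 (4.72 ± 0.70) and MIR850 (4.50 ± 0.39) and the B-box gene BBX16 (4.46 ± 0.69). The lowest were PIF3 itself (-4.78 ± 0.31), the oleosin gene OLEO3 (-4.50 ± 0.68), PIL1, NSP2 (-4.2 ± 1.28), a nitrile specifier gene, and ELIP1 (-3.79 ± 0.67), an early light-induced gene. NSP2 was not called without the first replicate of WT dark mock (adjusted p = 0.108), and without that library MIR5026 changed by 7.57. QQS was at 1.69 ± 0.538 CPM in WT dark mock and 55.5 ± 6.72 CPM in pifq dark mock. edgeR called 9250 of 20828 genes (4904 higher and 4346 lower) with n = 3 per group.

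Under ABA in darkness, camera called lists of growth genes lower in pifq than in WT. Expansins and XTH were lower in 16 and higher in 4 of 25 (4 higher and 17 lower adjusted over the list alone, camera adjusted p = 5.02e-07, adjusted p = 0.0709 with estimated correlation). XTH17 (-4.1 ± 0.38) and EXPA8 (-3.43 ± 0.22) were among the lower ones. SAUR genes were lower in 32 and higher in 14 of 64 (camera adjusted p = 0.0011, adjusted p = 0.395 with estimated correlation). Auxin genes were lower in 13 and higher in 3 of 24 (camera adjusted p = 0.000283, adjusted p = 0.359 with estimated correlation). PIF-induced genes were lower in 12 and higher in 1 of 14 (camera adjusted p = 6.44e-14, adjusted p = 0.0085 with estimated correlation). Gibberellin genes were lower in 9 and higher in 1 of 18 (camera adjusted p = 0.000571, adjusted p = 0.132 with estimated correlation). GA20OX1, a gibberellin synthesis gene, changed by -3.53 ± 0.42. AGP30 (5.91 ± 0.89), BGLU35 (5.74 ± 0.80) and BGLU34 (5.55 ± 0.71) were the highest named genes, and ATPMEPCRD (-5.60 ± 0.31), PIL1 (-5.45 ± 0.28) and UMAMIT17, a transporter gene (-5.38 ± 0.47), the lowest. Without the first replicate of WT dark ABA the change of AGP30 was 9.02. edgeR called 8258 of 20828 genes (4614 higher and 3644 lower) with n = 3 per group.

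In pifq in darkness ABA lowered many members of the growth lists. SAUR genes fell in 24 and rose in 12 of 64 (camera adjusted p = 0.104). SAUR16 went from 8.43 ± 1.64 to 1.12 ± 0.236 CPM. Expansins and XTH fell in 13 and rose in 6 of 25 (camera adjusted p = 0.00473, adjusted p = 0.321 with estimated correlation). EXPA8 went from 152 ± 19.3 to 15.2 ± 3.63 CPM. Auxin genes fell in 12 of 24 (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.588 with estimated correlation). Mitotic genes fell in 7 of 10 (0 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00513, adjusted p = 0.531 with estimated correlation), and stomatal lineage genes in 6 of 9 (camera adjusted p = 0.00221, adjusted p = 0.18 with estimated correlation). ABA receptors fell in 7 of 9 (0 higher and 8 lower adjusted over the list alone, camera adjusted p = 4.05e-05, adjusted p = 0.0402 with estimated correlation). The ABA-induced effector genes rose in 21 of 21 (camera adjusted p = 2.79e-25, adjusted p = 0.006 with estimated correlation). Clade A PP2C phosphatases rose in 9 of 9 (camera adjusted p = 8.33e-32, adjusted p = 0.000105 with estimated correlation) and the seed storage genes in 11 of 11 (camera adjusted p = 0.000283, adjusted p = 0.395 with estimated correlation). EM1, a late embryogenesis gene, changed by 8.70 ± 0.75 and AtMT4b by 8.09 ± 0.68. CBSX4 was 832-fold higher (95% counting interval 284 to 4037). AIR1 (-8.34 ± 0.29), CKX4 (-6.32 ± 0.33) and CYP735A2 (-6.11 ± 0.28) were among the lowest. CRK30 was 191-fold lower (95% counting interval 64.9 to 927). edgeR called 10132 of 20828 genes (5412 higher and 4720 lower) with n = 3 per group. Of the calls, 53.4% were higher, against 35.9% when libraries were scaled by their totals alone (3585 higher and 6394 lower).

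The interaction of ABA and genotype in darkness tested whether pifq responded otherwise than WT. EXPA8 stood at 141 ± 11 CPM in WT mock and 164 ± 43.3 CPM in WT ABA. With its fall in pifq, the interaction was -3.54 ± 0.29 (adjusted p = 4.82e-07). IAA6 (-4.38 ± 0.46), IAA19 (-3.08 ± 0.45), EXPA1 (-2.23 ± 0.22) and GA20OX1 (-3.06 ± 0.53) responded lower in pifq too. Among SAUR genes, SAUR16 (-2.55 ± 0.40, adjusted p = 0.000383) and SAUR1 (-2.29 ± 0.43) responded lower in pifq. SAUR76 (4.2 ± 0.72) and SAUR37 (adjusted p = 7.98e-05, with at most 3 counts in a group) responded higher. Of 64 SAUR genes 10 responded higher and 6 lower in pifq (12 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.963), so the list as a whole took neither direction. The number higher was 6 without the third replicate of WT dark ABA and 5 without the second replicate of pifq dark mock. The expansins and XTH gave 11 lower and 2 higher of 25 (6 higher and 12 lower adjusted over the list alone, camera adjusted p = 6.35e-06, adjusted p = 0.0975 with estimated correlation). The auxin genes gave 5 lower and 1 higher of 24 (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.00193, adjusted p = 0.432 with estimated correlation). The stomatal lineage gave 4 lower of 9 (0 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.000376, adjusted p = 0.126 with estimated correlation).

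Root hair genes and IRT1 went the other way. Root markers responded higher in pifq in 6 and lower in 2 of 13 (6 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00124, adjusted p = 0.395 with estimated correlation). The 2 lower were the endodermis genes CASP4 (-1.69 ± 0.44) and CASP2 (-1.47 ± 0.41). IRT1 fell to 0.321 ± 0.395 CPM in WT and 9.27 ± 3.37 CPM in pifq, an interaction of 5.50 ± 0.78 (adjusted p = 0.00021). The root hair genes EXPA18 and PRP3 fell with ABA in WT. In pifq edgeR called both higher, EXPA18 by 2.13 ± 0.48 (adjusted p = 0.00116) and PRP3 by 1.76 ± 0.44 (adjusted p = 0.00298), but for each the lowest ABA library lay below the highest mock library. A fit of these 6 libraries alone did not call PRP3. EXPA18 went from 3.87 ± 1.15 to 0.0825 ± 0.0989 CPM in WT. In pifq it went from 1.33 ± 0.95 to 5.70 ± 3.51 CPM (interaction 7.59 ± 0.93, adjusted p = 4.12e-05). PRP3 had an interaction of 5.22 ± 0.71, EXPA7 of 3.87 ± 0.63, COBL9 of 3.88 ± 0.55 and RSL4 of 2.75 ± 0.83. CASP2, CASP4, EXPA7 and RSL4, and the changes of EXPA18 and PRP3 in pifq, fell outside the rule and were chosen after their values were seen. RSL4 was not called without 6 of 12 libraries taken out in turn (adjusted p = 0.0528 to 0.145), and CASP2 not without 5 of 12 (adjusted p = 0.059 to 0.0811). The highest interactions by the rule were those of AGP30 (6.21 ± 1.07), BGLU35 (6.03 ± 0.93), EXPA17 (adjusted p = 0.000367, with at most 3 counts in a group), BGLU34 (5.86 ± 0.83) and IRT1. Their sizes rest on few counts, in the 3 WT dark ABA libraries 14, 1 and 2 for IRT1, 1, 0 and 3 for EXPA18, 28, 1 and 1 for AGP30, 4, 0 and 5 for BGLU35 and 7, 1 and 2 for BGLU34. The lowest were those of PME61 (-4.92 ± 0.46), UMAMIT17 (-4.48 ± 0.58) and ATPMEPCRD (-4.26 ± 0.37). CRK13 (-3.91 ± 0.82), a receptor-like kinase gene, and WSD1 (-3.83 ± 0.53), a wax ester synthase gene, followed. Without the first replicate of WT dark ABA the value of CRK13 was -2.40. ATPMEPCRD stood at 458 ± 64.0 and 372 ± 130.0 CPM in WT mock and ABA, and at 181 ± 25.9 and 7.65 ± 3.02 CPM in pifq.

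edgeR called 2376 of 20828 genes (1191 higher and 1185 lower) in this interaction with n = 3 in each of 4 groups, and 1530 without the second replicate of pifq dark mock. This interaction and that of ABA and light both used the WT libraries of dark mock and dark ABA. Across genes, the 2 interactions had a Pearson r of 0.616 and a covariance of 0.454. The mean r was 0.457 (0.44 to 0.486) and the mean covariance 0.107 in 10 simulations without effects, no baseline for real ones. Of called genes, 455 were higher in both, among them AGP30 and BGLU35, and 440 lower in both, among them EXPA8 and IAA6. Simulations made 0 such calls, too few to compare. Independent lists give 70 and 71. In opposite directions 24 were called, against 141.

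**Figure D3:**
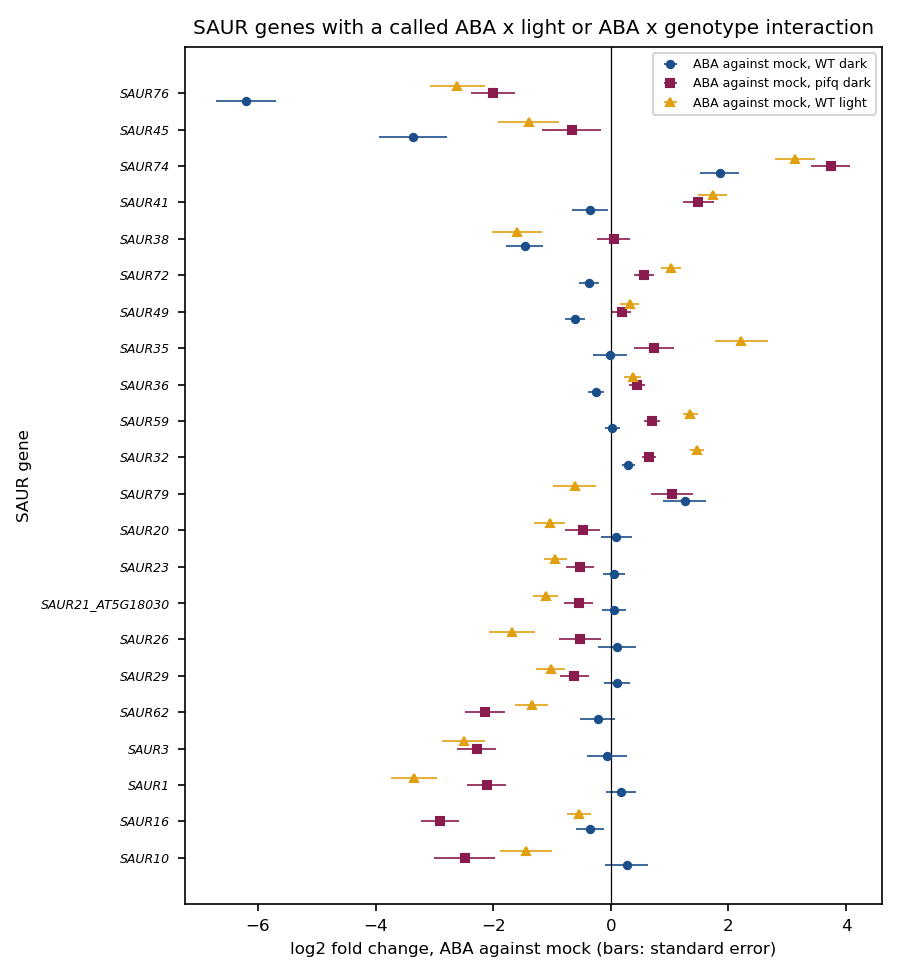
Log2 fold change of ABA against mock (horizontal axis, bars are standard errors) in WT dark, pifq dark and WT light for the SAUR genes with a called interaction of ABA with light or with genotype in darkness, ordered by the interaction with genotype. Genes with at most 3 counts in a group are left out. Genes at the bottom, such as SAUR16, fell in pifq dark, and SAUR76, at the top, fell further in WT dark than in pifq dark.

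**Figure D4:**
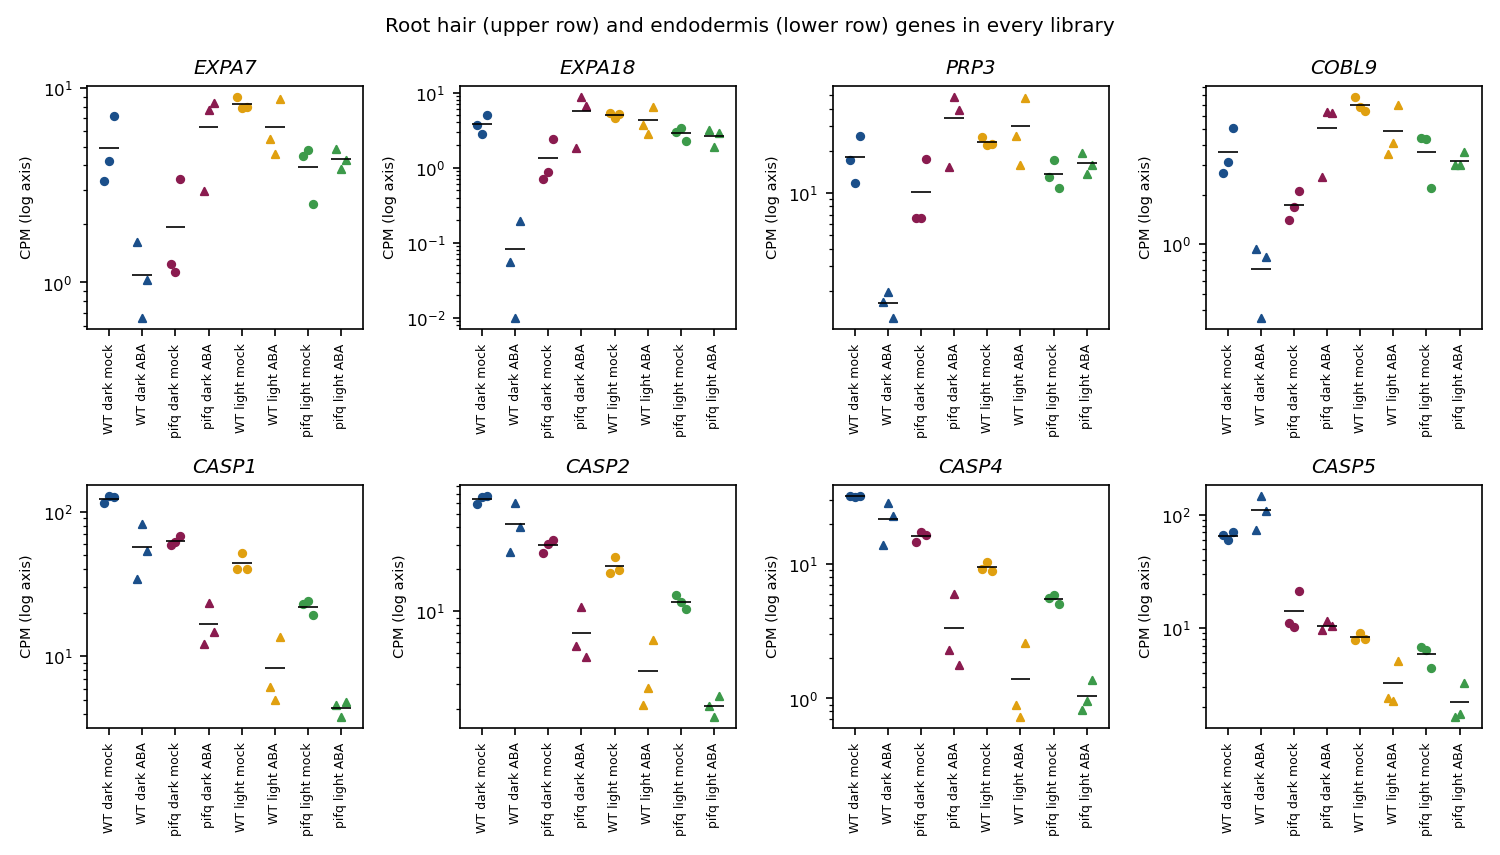
Level in CPM (log axis, values under 0.01 drawn at 0.01) of root hair genes (upper row) and endodermis genes (lower row) in each of the 24 libraries. Points are libraries (circles mock, triangles ABA) and black lines group means of 3. EXPA18 lies lower with ABA than with mock in WT dark and higher with ABA in pifq dark.

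In light, PIF-induced genes led the differences between pifq and WT. In light mock 12 of 14 PIF-induced growth and shade genes were lower in pifq and none was higher (0 higher and 14 lower adjusted over the list alone, camera adjusted p = 1.56e-30, adjusted p = 0.000296 with estimated correlation). IAA29, an auxin repressor gene of shade responses, went from 34.8 ± 10.3 to 0.543 ± 0.234 CPM (adjusted p = 3.3e-06). PIL1 was 23.5-fold lower (95% counting interval 7.71 to 117). Auxin genes were lower in 14 of 24 (0 higher and 17 lower adjusted over the list alone, camera adjusted p = 3.09e-17, adjusted p = 0.0202 with estimated correlation). YUC9 (-3.24 ± 0.49) and YUC8 (-2.13 ± 0.21), which make auxin, were among them. SAUR genes were lower in 16 and higher in 1 of 64 (2 higher and 25 lower adjusted over the list alone, camera adjusted p = 2.83e-10, adjusted p = 0.096 with estimated correlation). SAUR22 changed by -5.11 ± 0.49 and SAUR19 by -4.68 ± 0.43. SAUR19 to SAUR24 are near-identical copies, and how the counting assigned their reads is not given in the sources used here. Without these 6 copies, 10 SAUR genes were lower. QQS (5.82 ± 0.46), ACD6 (2.09 ± 0.46), a cell death regulator, and the ethylene synthesis gene ACS7 (2.04 ± 0.19) were the highest. edgeR called 2208 of 20828 genes (1174 higher and 1034 lower) with n = 3 per group, and 999 without the third replicate of pifq light mock. Under ABA in light it called 267 of 20828 genes (122 higher and 145 lower). The number lay between 100 (without the third replicate of WT light ABA) and 197 (without the second) with 1 library of these groups left out. Of those calls, 45.7% were higher, against 24.2% when libraries were scaled by their totals alone (78 higher and 244 lower). DESeq2 made 531 calls, 61.2% of them higher.

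Under ABA in light, QQS (4.03 ± 0.40), the 6-phosphogluconolactonase gene PGL5 (2.46 ± 0.35) and GH3.9 (1.62 ± 0.36) were highest in pifq. PIF3 (-3.29 ± 0.27) and SAUR22 (-3.51 ± 0.54) were among the lowest, and PIL1 was 13.3-fold lower (95% counting interval 4.26 to 67.0). PIF-induced genes were lower in 4 of 14 (0 higher and 8 lower adjusted over the list alone, camera adjusted p = 1.16e-26, adjusted p = 0.000533 with estimated correlation). SAUR genes were lower in 6 of 64 (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.00259, adjusted p = 0.438 with estimated correlation). Without SAUR19 to SAUR24 the number was 0, so these calls were of the near-identical copies. PIF family members were lower in 3 of 7 (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 1.77e-12, adjusted p = 0.000533 with estimated correlation), PIF3, PIF4 and PIF5, which are mutated in pifq. PIL1 was not called without the first replicate of pifq light ABA (adjusted p = 0.0556), and GH3.9 not without 4 of 6 libraries taken out in turn (adjusted p = 0.0857 to 0.158). Same-numbered WT and pifq libraries deviated from their group means together under light ABA, with Pearson r over genes of 0.39, 0.51 and 0.34. With the replicate number as a block edgeR called 338 genes. Fitted to these 6 libraries alone, with the block, it called 3924, in an alternative added after the data were seen.

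In pifq in light, ABA raised the lists of its own response again. The effector genes rose in 21 of 21 (camera adjusted p = 1.16e-26, adjusted p = 0.00261 with estimated correlation) and the clade A PP2C phosphatases in 9 of 9 (camera adjusted p = 7.36e-30, adjusted p = 0.000105 with estimated correlation). ABA synthesis and catabolism rose in 7 of 12 (camera adjusted p = 1.95e-08, adjusted p = 0.000721 with estimated correlation). The seed storage genes rose in 11 of 11 (camera adjusted p = 0.000103, adjusted p = 0.392 with estimated correlation). SESA1 was 3005-fold higher (95% counting interval 539 to 118755), or 1101-fold without the second replicate of pifq light ABA, and SESA5 changed by 9.76 ± 1.55. SAUR genes fell in 18 and rose in 12 of 64 (camera adjusted p = 0.888). Expansins and XTH fell in 11 and rose in 4 of 25 (4 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.0685). CRK30 was 2141-fold lower (95% counting interval 384 to 84604). EARLI1, a lipid transfer protein gene, changed by -6.97 ± 0.56. edgeR called 9736 of 20828 genes (4937 higher and 4799 lower) with n = 3 per group. Of the calls, 50.7% were higher, against 31.1% when libraries were scaled by their totals alone (3284 higher and 7285 lower). The responses of WT and pifq in light, which share no library, had a Pearson r of 0.913 across genes. There were 3558 genes higher in both (1038 for independent lists), 3081 lower in both (909) and 10 called in opposite directions (1945).

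The interaction of ABA and genotype in light was called for few genes. ACS7 (-2.18 ± 0.27, adjusted p = 0.00104), the flagellin receptor gene FLS2 (-2.23 ± 0.29) and ESM1 (-1.61 ± 0.26) responded lower in pifq. The fatty acid reductase gene FAR1 (2.47 ± 0.38), PAR2 (1.18 ± 0.24) and the protein kinase gene SR1 (1.08 ± 0.20) responded higher. With 1 library left out, calls were lost by PAR2 without 11 of 12 libraries taken out in turn (adjusted p = 0.0565 to 0.15) and SR1 without 8 of 12 libraries taken out in turn (adjusted p = 0.0504 to 0.0799). The same held for ESM1 without 2 of 12 libraries taken out in turn (adjusted p = 0.0568 to 0.0639) and FAR1 without the second replicate of pifq light mock (adjusted p = 0.0639). No SAUR gene was called by edgeR singly, 9 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher. Camera called the SAUR list higher (camera adjusted p = 0.000754, adjusted p = 0.383 with estimated correlation). edgeR called 45 of 20828 genes (18 higher and 27 lower) with n = 3 in each of 4 groups, against 2100 at an unadjusted p under 0.05. DESeq2 called 149. With 1 library left out the number lay between 4 (without the second replicate of pifq light mock) and 74 (without the first). Of the calls, 40.0% were higher, against 26.2% when libraries were scaled by their totals alone (11 higher and 31 lower). Camera called auxin genes higher with 0 genes called singly (2 higher and 0 lower adjusted over the list alone, camera adjusted p = 4.03e-08, adjusted p = 0.132 with estimated correlation). It called PIF-induced genes higher with 1 (6 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00385, adjusted p = 0.321 with estimated correlation), and with 0 when libraries were scaled by their totals alone.

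Light against darkness in mock gave the greening of WT. Nuclear photosynthesis genes were higher in light in 26 of 26 (camera adjusted p = 1.27e-16, adjusted p = 0.173 with estimated correlation). Chlorophyll genes were higher in 12 and lower in 1 of 14 (camera adjusted p = 1.31e-08, adjusted p = 0.132 with estimated correlation). PIF-induced genes were lower in 11 and higher in 2 of 14 (camera adjusted p = 2.74e-05, adjusted p = 0.126 with estimated correlation). Expansins and XTH were lower in 15 and higher in 5 of 25 (camera adjusted p = 0.00619, adjusted p = 0.323 with estimated correlation). Stomatal lineage genes were higher in 8 of 9 (camera adjusted p = 0.00237, adjusted p = 0.179 with estimated correlation). The protein kinase gene CIPK20 was at least 3083-fold higher, CYP71A22 at least 601-fold higher and PPT2, a plastid translocator gene, at least 377-fold higher. BETA-TIP was at least 236-fold lower and HEC2, a bHLH gene, changed by -7.74 ± 0.73 and OLEO3 by -7.27 ± 0.95. edgeR called 13507 of 20828 genes (6806 higher and 6701 lower) with n = 3 per group. Of the calls, 50.4% were higher, against 37.6% when libraries were scaled by their totals alone (5153 higher and 8570 lower).

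In pifq the photosynthesis genes were higher in light in 23 of 26 (24 higher and 0 lower adjusted over the list alone, camera adjusted p = 4.29e-05, adjusted p = 0.592 with estimated correlation). Auxin genes were lower in 21 of 24 (camera adjusted p = 5.17e-07, adjusted p = 0.173 with estimated correlation). All 14 PIF-induced genes were lower (camera adjusted p = 6.56e-08, adjusted p = 0.0614 with estimated correlation). CIPK20 changed by 9.68 ± 0.40, CYP706A6, a cytochrome P450 gene, was 2296-fold higher (95% counting interval 635 to 18967) and ACD6 1836-fold higher (95% counting interval 329 to 72583). HEC2 (-6.25 ± 0.91), IAA20 (-5.40 ± 0.43) and ATPMEPCRD (-5.34 ± 0.32) were lowest. edgeR called 11940 of 20828 genes (6047 higher and 5893 lower) with n = 3 per group. Of the calls, 50.6% were higher, against 34.1% when libraries were scaled by their totals alone (4195 higher and 8113 lower). Scaled by library totals alone, the median log2 change of all genes was -0.104 for ABA in WT light, -0.115 in pifq dark and -0.185 in pifq light, -0.181 for light in WT and -0.196 for light in pifq.

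The interaction of genotype and light in mock tested whether light changed pifq otherwise than WT. Photosynthesis genes responded less to light in pifq in 24 of 26 (camera adjusted p = 1.89e-25, adjusted p = 0.0975 with estimated correlation). So did chlorophyll genes in 12 of 14 (0 higher and 13 lower adjusted over the list alone, camera adjusted p = 9.46e-13, adjusted p = 0.0685 with estimated correlation) and stomatal lineage genes in 8 of 9 (camera adjusted p = 9.16e-12, adjusted p = 0.00353 with estimated correlation). LHCB6 had an interaction of -2.40 ± 0.28 and KAT1, a guard cell channel gene, of -2.84 ± 0.24. Auxin genes responded lower in 8 of 24 (0 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.000483, adjusted p = 0.371 with estimated correlation). SAUR genes responded lower in 10 and higher in 4 of 64 (5 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.625). The number of SAUR genes higher was 7 without the third replicate of pifq dark mock. Heat shock genes responded higher in 3 of 7 (6 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.000116, adjusted p = 0.201 with estimated correlation). PIF family members responded lower in 5 of 7 (camera adjusted p = 7.97e-06, adjusted p = 0.0102 with estimated correlation), and 4 of the 7 are mutated in pifq. IAA29 (-5.78 ± 0.71, adjusted p = 1.36e-05), BBX16 (-4.72 ± 0.78) and CYP96A12 (-4.52 ± 0.47) were lowest. CYP82F1 (3.32 ± 0.68), ELIP1 (3.31 ± 0.95) and DAA1 (3.29 ± 0.49) were highest. ELIP1 was not called without 2 of 12 libraries taken out in turn (adjusted p = 0.057 to 0.0601). edgeR called 3836 of 20828 genes (1384 higher and 2452 lower) with n = 3 in each of 4 groups. In mock, 3878 genes, LHCB6 among them, were higher both in pifq against WT in darkness and in light against darkness in WT. There were 3317, PIL1 among them, lower in both and 322 opposite. The 3 numbers for independent lists are 1602, 1398 and 2998. Both comparisons used the WT dark mock libraries as control. Their Pearson r was 0.735 and covariance 0.807. In 10 simulations without effects, no baseline for real ones, mean r was 0.471 and covariance 0.039.

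The last interaction, of all 3 factors, asked whether the difference between pifq and WT in the ABA response was itself unlike in light and darkness. EXPA8 (4.1 ± 0.41, adjusted p = 4.42e-05), PME61 (5.81 ± 1.08) and ATPMEPCRD (5.77 ± 1.01) were highest. BGLU35 (-6.45 ± 1.27), BGLU34 (-6.40 ± 1.14) and AGP30 (-6.18 ± 1.42) were lowest. AGP30 was not called without the third replicate of WT dark ABA (adjusted p = 0.0527), and without the first its value was -9.28. Expansins and XTH were higher in 6 and lower in 1 of 25 (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 7.72e-06, adjusted p = 0.0975 with estimated correlation). Auxin genes were higher in 5 of 24 (7 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.13e-07, adjusted p = 0.135 with estimated correlation). Gibberellin genes were higher in 2 of 18 (7 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.000238, adjusted p = 0.119 with estimated correlation). Root markers were lower in 5 of 13 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.605 with estimated correlation). SAUR genes gave 3 higher and 3 lower of 64 (5 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.178). The number higher was 5 without the first replicate of WT dark ABA. The number lower was 1 without the third replicate of WT light ABA and 1 without the second replicate of pifq dark mock. edgeR called 709 of 20828 genes (385 higher and 324 lower) with n = 3 in each of 8 groups.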

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

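Each result of this part is given because an effect of ABA or light differed between groups by the test of an interaction. Tests chosen after the results were seen were those of root tissue, WT RNA in pifq, reads outside the insertions, depth and scaling factors. So were the splits with equal numbers of exchanged labels. The counts of all other splits and the test of library totals were chosen before.

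In WT, ABA and light interacted in 2480 genes by edgeR, with 9 SAUR genes higher and 11 lower. Log2 interactions were 5.15 (BGLU35), -3.58 (IAA6), 5.21 (EXPA18), 5.53 (AGP30), -1.56 (PYL4), -2.00 (EXPA8), -4.06 (ATPMEPCRD), -2.99 (EXPA5), -3.57 (PME61), 3.82 (PRP3), -4.35 (MSRB7), -3.76 (FBA5), -3.26 (IAA29), -3.53 (SAUR1) and -3.66 (GER3). The edgeR adjusted p was 0.00045 (BETA-TIP), 0.00109 (EXPA17) and 0.0235 (AIR1), with at most 3 counts in a group. Camera gave adjusted p-values of 0.0334 (ABA receptor, lower), 0.000885 (expansin and XTH, lower), 0.0104 (auxin, lower), 0.0123 (mitotic, lower) and 0.00513 (stomatal lineage, lower). With an estimated correlation the adjusted p was, in that order, 0.314, 0.217, 0.542, 0.592 and 0.22, so none of these calls held. Of 100 splits of the 12 libraries, the real one included, 11 called as many genes, so chance cannot be excluded by this count. The highest other split called 10677, several times the real number, which points to a structure of the samples, here their main effects. Of the 11, all but the real one exchanged unequal numbers of labels between conditions, so that a main effect entered the contrast. Among the 40 with equal numbers, 1, the real one, called as many (2.5%).

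In darkness, ABA and genotype interacted in 2376 genes by edgeR, with 10 SAUR genes higher and 6 lower. Log2 interactions were 3.87 (EXPA7), 2.75 (RSL4), 5.86 (BGLU34), 6.03 (BGLU35), -4.38 (IAA6), 7.59 (EXPA18), -2.23 (EXPA1), 6.21 (AGP30), -3.54 (EXPA8), -4.26 (ATPMEPCRD), -1.47 (CASP2), -3.08 (IAA19), -4.92 (PME61), 5.22 (PRP3), -4.48 (UMAMIT17), 5.50 (IRT1), -3.91 (CRK13), -3.06 (GA20OX1), -2.29 (SAUR1), -2.55 (SAUR16), -1.69 (CASP4), 4.2 (SAUR76), -3.83 (WSD1) and 3.88 (COBL9). The edgeR adjusted p was 0.000367 (EXPA17) and 7.98e-05 (SAUR37), with at most 3 counts in a group. Camera gave adjusted p-values of 0.012 (clade A PP2C, higher), 6.35e-06 (expansin and XTH, lower), 0.00193 (auxin, lower), 0.00124 (root marker, higher) and 0.000376 (stomatal lineage, lower). With an estimated correlation the adjusted p was, in that order, 0.333, 0.0975, 0.432, 0.395 and 0.126, so none of these calls held. Of 100 splits of the 12 libraries, the real one included, 11 called as many genes, so chance cannot be excluded by this count. The highest other split called 7658, several times the real number, which points to the same structure. Of the 11, all but the real one exchanged unequal numbers, as above. Of the 40 with equal numbers, only the real one called as many (2.5%, same limit).

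In light, ABA and genotype interacted in 45 genes by edgeR. Log2 interactions were -1.61 (ESM1), 1.18 (PAR2), -2.18 (ACS7), 1.08 (SR1), 2.47 (FAR1) and -2.23 (FLS2). Camera gave adjusted p-values of 0.000754 (SAUR, higher), 0.00385 (PIF-induced, higher), 4.03e-08 (auxin, higher), 0.000206 (gibberellin, higher), 0.000139 (photosynthesis, higher), 0.0227 (chlorophyll, higher) and 0.0366 (mitotic, higher). With an estimated correlation the adjusted p was, in that order, 0.383, 0.321, 0.132, 0.116, 0.614, 0.614 and 0.647, so none of these calls held. Of the 26 photosynthesis genes, edgeR called 0, and 0 had an unadjusted p under 0.05. Of 100 splits of the 12 libraries, the real one included, 9 called as many genes, so chance cannot be excluded by this count. The highest other split called 772, several times the real number, which points to the same structure. Of the 9, all but the real one exchanged unequal numbers of labels, as above. Of the 40 with equal numbers, only the real one called as many (2.5%, same limit).

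In mock, genotype and light interacted in 3836 genes by edgeR, with 4 SAUR genes higher and 10 lower. Log2 interactions were -2.40 (LHCB6), 3.29 (DAA1), -4.72 (BBX16), 3.32 (CYP82F1), 3.31 (ELIP1), -5.78 (IAA29), -4.52 (CYP96A12) and -2.84 (KAT1). Camera gave adjusted p-values of 0.0498 (ABA effector, higher), 0.000483 (auxin, lower), 1.89e-25 (photosynthesis, lower), 9.46e-13 (chlorophyll, lower), 0.0322 (dark starvation, higher), 0.000116 (heat shock, higher), 9.16e-12 (stomatal lineage, lower) and 7.97e-06 (PIF family, lower). With an estimated correlation the adjusted p was, in that order, 0.647, 0.371, 0.0975, 0.0685, 0.323, 0.201, 0.00353 and 0.0102, and of these lists the call held for the stomatal lineage and PIF family lists, though 4 of the 7 PIF family genes are mutated in pifq. Of 100 splits of the 12 libraries, the real one included, 11 called as many genes, so chance cannot be excluded by this count. The highest other split called 6777. Of the 11, all but the real one exchanged unequal numbers, as above. Of the 40 with equal numbers, only the real one called as many (2.5%, same limit).

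All 3 factors interacted in 709 genes by edgeR, with 3 SAUR genes higher and 3 lower. Log2 interactions were -6.40 (BGLU34), -6.45 (BGLU35), -6.18 (AGP30), 4.1 (EXPA8), 5.77 (ATPMEPCRD) and 5.81 (PME61). Camera gave adjusted p-values of 0.0127 (PIF-induced, higher), 7.72e-06 (expansin and XTH, higher), 1.13e-07 (auxin, higher), 0.000238 (gibberellin, higher), 0.011 (brassinosteroid, higher), 0.0352 (chlorophyll, higher), 0.0408 (mitotic, higher), 0.0254 (root marker, lower) and 0.000571 (stomatal lineage, higher). With an estimated correlation the adjusted p was, in that order, 0.392, 0.0975, 0.135, 0.119, 0.371, 0.645, 0.648, 0.605 and 0.132, so none of these calls held. Of 100 splits of the 24 libraries, the real one included, 3 called as many genes, a share under 0.05. The highest other split called 1134. Of the 3, 1 exchanged unequal numbers of labels, as above. Among the 30 with equal numbers, the real one included, 2 called as many (6.67%, not under 5%), so chance is not excluded.

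For the comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05, and only the real one (1 of 10) reached the real count. Genes called in the real split and the highest other were 8385 and 18 for ABA in WT dark, 8327 and 0 for ABA in WT light, 10132 and 1 for ABA in pifq dark, 9736 and 0 for ABA in pifq light, 9250 and 0 for pifq against WT in dark mock, 8258 and 300 for dark ABA, 2208 and 7 for light mock, 267 and 8 for light ABA, 13507 and 0 for light against darkness in WT and 11940 and 0 for light against darkness in pifq.

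In darkness, 5 root hair genes (EXPA7, EXPA18, RSL4, PRP3 and COBL9) changed with ABA by -5.47 to -1.79 in WT. The median change of CASP1 to CASP5 (endodermis) was -0.60, above each root hair gene by more than the CASP spread. CASP1 to CASP4 fell with ABA in pifq too, so they do not gauge the share of root tissue, which stays open. RSL4 was not called in WT without 3 of the 6 libraries taken out in turn (edgeR adjusted p = 0.061 to 0.147). One scaling factor per library would move all genes alike, but the median interaction of ABA and genotype was -1.16 for CASP1 to CASP5, below that of each root hair gene by more than their spread. A change in root hairs that differs between the genotypes stays open as an untested biological hypothesis.

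Expansin and XTH genes responded lower to ABA in pifq than in WT in darkness. By library totals alone 10 were called lower, by TMM 11, with all-gene medians of -0.009 and -0.006. Medians this close cannot test scaling, nor can the 1191 genes called higher and 1185 lower, as TMM centres them. A lower depth of the WT dark libraries is argued against, as they held 107% of the counts of the pifq dark libraries. A dependence of these genes on PIF proteins under ABA stays open as a hypothesis, since the mutation is not separated from the different growth of the seedlings.

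PIF1 and PIF4 counts were higher in pifq than in WT in dark mock. WT RNA mixed into these libraries, or WT libraries among them, could not raise PIF1 above WT. The lowest pifq library held 2.2 times the PIF1 level of the highest WT library. Reads from parts of the genes outside the insertions cannot be told apart from whole transcripts, as counts per gene show no position; the log2 change of PIF1 was 1.28. Feedback on PIF1 and PIF4 by the absent PIF proteins stays open and was not tested, and in light mock PIF4 was lower in pifq than in WT (105 to 118 against 214 to 257 CPM).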

How the results depend on the processing

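The replicate block on only the samples compared and the shortened SAUR lists were tried only after the data were seen. No named gene with a call, and no list called by camera, reversed its direction under the alternatives run on it. The majority of called genes did turn between higher and lower, in 8 of 15 contrasts with RLE size factors, 9 with library totals and 9 with DESeq2. Of the named genes with a call, all 187 kept it with DESeq2, RLE size factors, the filter of 1 CPM and no organelle genes. Calls were lost by 16 with limma-voom, 10 of 184 with only the samples compared, 4 with the replicate block on those samples, 2 with library totals, 3 with the 2-fold limit, 1 with the block and 1 with no filter. With 1 library left out 54 of 1578 tests lost it. Of 148 named results with a log2 change, the fold moved by over 1.5 times without 1 library in 51, and the log2 change itself in 5. Counts of genes that moved by over 1.5 times are given with the value of the main test in brackets. With a limit of 2-fold, fewer genes pass by construction: ABA WT dark 3014 (8385), ABA WT light 3439 (8327), ABA pifq dark 3583 (10132), ABA pifq light 3705 (9736), pifq dark mock 2430 (9250), pifq dark ABA 2404 (8258), pifq light mock 369 (2208), pifq light ABA 95 (267), light WT 6025 (13507), light pifq 4319 (11940), ABA by light 1303 (2480), ABA by genotype dark 1198 (2376), ABA by genotype light 23 (45), genotype by light 1615 (3836), ABA WT dark (SAUR higher) 3 (6), ABA pifq dark (SAUR higher) 4 (12), pifq dark mock (SAUR lower) 13 (24), pifq light mock (SAUR higher) 0 (1), light WT (SAUR higher) 11 (18), light pifq (SAUR higher) 8 (15), ABA by genotype dark (SAUR higher) 6 (10) and genotype by light (SAUR higher) 2 (4). By DESeq2, the counts were pifq light ABA 531 (267), ABA by genotype light 149 (45), 3 factors 1110 (709), pifq light mock (SAUR higher) 2 (1), pifq light ABA (SAUR higher) 2 (0) and ABA by genotype light (SAUR higher) 1 (0). By limma-voom, the counts were pifq light ABA (SAUR higher) 1 (0). With the replicate block, the counts were pifq light mock (SAUR higher) 2 (1) and pifq light ABA (SAUR higher) 1 (0). With only the samples compared, the counts were pifq light ABA 155 (267), ABA by genotype light 11 (45) and pifq light mock (SAUR higher) 2 (1). With the replicate block and only the samples compared, the counts were pifq light ABA 3924 (267), ABA by genotype light 99 (45), pifq light mock (SAUR higher) 2 (1) and pifq light ABA (SAUR higher) 4 (0). Without SAUR19 to SAUR24, the counts were pifq light mock (SAUR lower) 10 (16) and pifq light ABA (SAUR lower) 0 (6). Fewer libraries enter a fit of the samples compared, and fewer genes a shorter list. For the other changes the cause was not tested. Of the 135 list tests called by camera, 25 were called with an estimated correlation, 120 kept their call with fry and 135 with the replicate block.

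With 1 library left out in turn, and so fewer libraries, the lowest and highest counts were 999 to 2268 for pifq light mock (2208), 100 to 197 for pifq light ABA (267), 1530 to 2734 for ABA by genotype dark (2376), 4 to 74 for ABA by genotype light (45), 9 to 14 for ABA WT dark (SAUR lower) (14), 0 to 2 for pifq light mock (SAUR higher) (1), 0 to 1 for pifq light ABA (SAUR higher) (0), 7 to 17 for ABA by light (SAUR lower) (11), 5 to 11 for ABA by genotype dark (SAUR higher) (10), 3 to 7 for genotype by light (SAUR higher) (4), 1 to 4 for 3 factors (SAUR lower) (3) and 2 to 5 for 3 factors (SAUR higher) (3). With the replicate block pifq against WT gave 9597 genes in dark mock and 338 under light ABA, where the numbers were taken to pair the libraries. In the 8 other comparisons of 2 groups at least 1 pair had an r of 0.1 or less (range -0.16 to 0.3), so the libraries share only a number. In 1 of these, pifq against WT in dark ABA, each library correlated best with its own number. Without the gene whose product is an ARM repeat protein no SAUR count moved by over 1.5 times. The block moved no other count of genes by over 1.5 times and ended no list call. Depth limits genes with at most 3 counts over a group, for which no fitted size is given.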

Other observations

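In light, ABA raised PIF genes in both genotypes. PIF family members rose in 6 of 7 in WT light (camera adjusted p = 0.0124, adjusted p = 0.17 with estimated correlation) and in 6 in pifq light (camera adjusted p = 0.0123, adjusted p = 0.167 with estimated correlation). In pifq dark the list was not called: 4 rose and 1 fell (camera adjusted p = 0.066), the latter PIF1 (-0.46 ± 0.10), chosen after its value was seen. In WT dark PIF4 changed by 1.15 ± 0.12 and PIF3 by 0.95 ± 0.23. Enzymes of flavonoid synthesis went both ways with ABA in WT dark: TT4, the chalcone synthase gene, changed by -2.05 ± 0.29 and TT5, the chalcone isomerase gene, by 2.03 ± 0.13. HSP18.2, a small heat shock gene, changed by -1.57 ± 0.32 there and HSP70 by 1.28 ± 0.44. HSP70 was not called without the third replicate of WT dark ABA (edgeR adjusted p = 0.0697) or of WT dark mock (adjusted p = 0.116). In dark mock, photomorphogenesis regulators were lower in pifq in 7 and higher in 3 of 15 (camera adjusted p = 0.0498, adjusted p = 0.541 with estimated correlation).

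The ABA response of pifq in darkness may be closer to that of WT in light than to that of WT in darkness, a hypothesis written down before the correlations were seen. Over all tested genes, which are not independent, the Pearson r with WT light was 0.807 and with WT dark 0.765, and these pairs of comparisons share no library. A check chosen after that result was seen used group means of log2 CPM. There Pearson r was 0.815 and 0.789, and with each of 18 libraries left out in turn the difference lay between 0.012 and 0.048, above 0 in 18 of 18. The difference is small and rests on Pearson r, since ranks and calls did not clearly set the pairs apart. Light and age were not separated.

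For the 2 overlaps of contrasts that share libraries, neither the excess of calls over independent lists nor the simulations measure a shared effect. Part of the excess can come from shared controls.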
